A study of Mus musculus with 2 samples.

How the data were processed

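Bone marrow was profiled from male wild-type mice aged 8 to 10 weeks, in 1 control library and 1 library from the middle cerebral artery occlusion (MCAO) model of stroke. Per the labels' protocols, marrow was flushed from tibias and femurs, strained, treated with red cell lysis buffer and loaded as all marrow cells, with no sort, on the BD Rhapsody microwell system, and whole-transcriptome libraries were sequenced as paired ends on an Illumina NovaSeq instrument. The submitters' processing notes name fastp, STAR, UMI-tools and Seurat 4.0.6 and the mouse build mm10. The order and settings of these tools, the gene annotation behind the counts and any filter on cells were not given in the sources used here. The number of animals per library, the time after occlusion and the handling of the control animals were not given either.

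The authors deposited 1 table of natural log values, which holds 25943 genes and 10610 cells, and per the labels it covers both libraries. Each value was the natural log of 1 plus 10000 times the gene's share of the cell's UMIs. This was read from the values, since the linear values of every cell summed to 10000. The smallest step in each cell therefore gave the worth of 1 UMI, and whole UMIs were recovered for 100% of the 19373615 values above 0, with a tolerance of 0.01 UMIs. Cells were assigned to a library by the start of their column names, which are the Mandarin words for control and stroke and were mapped by translation. 2448 genes had no UMI in any cell. The table held 0 genes named as mitochondrially encoded, so the list of 13 such genes fixed as a sign of RNA quality had 0 measured members and gave no result.

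The control library held 5212 cells and 25886279 UMIs, with a median of 3344 UMIs per cell. The MCAO library held 5398 cells and 35401492 UMIs, with a median of 4952 per cell. The 20 most abundant genes took 17.0% of the control UMIs and 18.2% of the MCAO UMIs. No filter on cells was added. Doublets were scored against simulated doublets, 2 per cell, with the threshold at the minimum between the modes of the simulated scores. This marked 40 control cells (0.768%) and 56 MCAO cells (1.04%), and 35.0% and 36.4% of the simulated doublets. Marked cells were kept in the reported values and left out as an alternative. They included all 27 cells of cluster 25, which was named B-cell-like and held 14 control and 13 MCAO cells.

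The deposited table gave no cell types, so classes were rebuilt, and their names and borders may differ from those of the study. Cells of both libraries were clustered together with no batch integration, on the 2000 most variable genes, 30 principal components, 20 neighbours and a shared-neighbour graph, by the Leiden method at resolution 1, which gave 26 clusters. A cluster was named from 20 marker sets fixed before the data were examined. A marker counted as detected when it was above 0 in at least 20% of the cluster's cells. A name needed at least 3 detected markers. It went to the class with most markers among the 10 leading genes if that class had more than 1 there, with ties set by marker score. Otherwise it went to the class with the highest marker score. This scoring rule was set after the data were seen. Cluster 17 stayed unnamed, with 66 control and 47 MCAO cells led by Prg2 and Ear1. Cd177 was left out of the markers. The B-lineage-like class joined the pro-B-or-pre-B-like, B-cell-like and plasma-cell-like classes, and the neutrophil-like class joined 3 stages (pre-neutrophil, immature and mature). Clusters 14 and 20, named pro-B-or-pre-B-like and monocyte-like, had no marker of any class among their 10 leading genes and were named by marker score alone. Clusters 7 (pro-B-or-pre-B-like), 8 (B-cell-like), 12 and 18 (both erythroid-like) had 1 marker of their class there and were also named by score.

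The level of a gene in a class was its summed UMIs per 10000 UMIs of the class, with an exact Poisson interval on the sum at 95% confidence. Shares of cells have exact binomial (Clopper-Pearson) intervals. Ratios are the MCAO library over the control library, with a pseudocount of 0.02 per 10000 for log2 ratios and none for folds. A fold against 0 UMIs was computed against a floor of 3 UMIs over the class. With 1 library per group no test between conditions was possible, so no p-value was computed. Genes were ranked when they had at least 50 UMIs over both libraries and were above 0 in at least 2% of the class's cells in 1 library. The genes named are the 12 highest and 12 lowest by log2 ratio in mature-neutrophil-like cells, the 4 highest and 4 lowest in other classes with at least 100 cells in each library, Cd177, and up to 4 members furthest from 0 of any list described. Haemoglobin genes, antigen receptor segments and gene models with Gm or Rik names were not ranked. 1 gene that this rule takes in mature-neutrophil-like cells is not reported here. Genes named outside this rule are said to be chosen after their values were seen.

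The lists fixed before the data were examined numbered 21: primary, secondary and gelatinase granules, neutrophil surface receptors, marrow retention and egress, interferon response, NF-kB inflammatory genes, glucocorticoid response, G-CSF and STAT3 response, alarmins, glycolysis and hypoxia, NADPH oxidase, cell cycle, MHC class I, MHC class II, B-cell development, immediate early and heat shock genes, apoptosis, haemoglobin, cytosolic ribosomal proteins and the mitochondrially encoded genes. A list's value is the median log2 ratio of its members past the floor, with at least 3 required. Its percentile was taken among 10000 random lists of the same size, in which each member was replaced by 1 of the 100 genes nearest in mean level. Some lists share genes. Ltf, Lcn2, Camp and Ngp of the secondary granule list also named the immature class, and Cybb and Cyba stand in both the secondary granule and NADPH oxidase lists. Cxcr2 and Csf3r are among the genes in both the surface receptor and retention lists, and Anxa1 is in both the glucocorticoid and alarmin lists.

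Cells with and without a Cd177 UMI were compared within each library, stage and 5 depth bins, keeping bins with at least 20 cells on each side and averaging over bins. The 8 highest and 8 lowest genes with the same sign in both libraries were named, by the smaller of the 2 ratios. Shares of cells with Cd177 were also computed after thinning each cell to 1000 UMIs. Gene positions came from GENCODE release M21, which uses the same build as the notes name and held 25389 of the 25943 symbols (97.9%); this annotation may differ from that of the authors. Whether the counting used strand was not given in the sources used here.

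Alternatives fixed before the data were examined covered the clustering resolution, the number of variable genes, doublets, a minimum of 1000 UMIs, classes assigned cell by cell, the pseudocount, the level, centring, the floor and the matching of random lists. Others were chosen after seeing the data and covered single clusters, depth bands, other denominators and B-lineage classes apart. The ranking and list steps were tested on simulated data drawn from the mature-neutrophil-like means, with 7345 genes run. All 24 genes at the ranked ends were changed ones, 2-fold changes were recovered at a median log2 of 0.92 and -0.96, and 4-fold changes at 1.95 and -1.85. In that simulation 8.50% of 200 unchanged lists lay outside the central 95% of random lists. For the Cd177 contrast, with 5514 genes run, 93.1% to 100% of changed genes kept their true sign. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, igraph 0.11.9, leidenalg 0.10.2, scikit-image 0.26.0 and matplotlib 3.10.9.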

Results

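The data collected were whole-transcriptome profiles of single bone marrow cells from male wild-type mice. Each mRNA molecule carried a cell barcode and a unique molecular identifier (UMI), which allows molecules to be counted. 1 library came from the control condition and 1 from mice after middle cerebral artery occlusion (MCAO), a stroke model in which an artery that feeds the brain is blocked. The control library held 5212 cells with a median of 3344 UMIs and 1315 genes per cell, and its cells ranged from 310 to 58726 UMIs. The MCAO library held 5398 cells with a median of 4952 UMIs and 1600 genes per cell, over a range of 539 to 62637 UMIs. Its median depth was therefore 1.48 times that of the control library. Each group had 1 library, so no difference between the conditions has a replicate check, and the intervals in brackets are 95% intervals that cover counting error only. Percentiles of gene lists among random lists are a description of these 2 libraries. Free RNA from lysed cells was visible in both libraries. Haemoglobin genes were higher in the MCAO library in 9 of 9 compared classes, with medians from 0.58 to 0.99 on the log2 scale, and B-cell development genes were lower in 9 of 9.

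The series compared marrow after stroke with control marrow, and the makeup of the marrow was described first. Neutrophil-like cells were the largest class in both libraries, with 46.4% [45.03 to 47.8] of control cells and 51.4% [50.1 to 52.8] of MCAO cells. This difference of 5.05 percentage points was 0.865 points without cluster 9, a setting chosen after seeing the data. B-lineage-like cells made up a smaller share of the MCAO library, at 14.1% [13.2 to 15.1] against 26.7% [25.6 to 28.0] of the control library. The shares of a library depend on each other, so this gap raises the other MCAO shares. Of the 5212 control and 5398 MCAO cells, 1394 and 762 were B-lineage-like and 2418 and 2777 neutrophil-like. Among cells that were not B-lineage-like, the neutrophil-like share was therefore smaller in the MCAO library. Monocyte-like cells made up 15.0% [14.04 to 16.0] of MCAO cells and 10.1% [9.29 to 10.9] of control cells. The gap in B-lineage-like cells lay mainly in pro-B-or-pre-B-like cells, the marrow precursors of B cells, which numbered 700 in the control library (13.4% [12.5 to 14.4]) and 199 in the MCAO library (3.69% [3.20 to 4.22]). B-cell-like cells differed less, at 13.1% [12.2 to 14.1] and 10.3% [9.52 to 11.2]. Pro-B-or-pre-B-like cells were 50.2% of control and 26.1% of MCAO B-lineage-like cells. These shares can be set by the red cell lysis, by the loading of all marrow cells and by the depth gap. Among cells with at least 2000 UMIs, a choice made after seeing the data, the B-lineage-like difference was -8.98 percentage points, against -12.6 over all cells.

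Early cells of the granulocyte line held larger shares of the MCAO library. The smaller B-lineage-like share of that library is part of these gaps. Promyelocyte-like cells, in which primary granule proteins are made, were 3.55% [3.06 to 4.09] of control and 5.11% [4.54 to 5.74] of MCAO cells, and pre-neutrophil-like cells, which still divide, were 5.12% [4.54 to 5.76] and 8.06% [7.35 to 8.82]. Immature-neutrophil-like cells held 13.2% and 15.2%, and mature-neutrophil-like cells 28.1% and 28.2%. Within the neutrophil-like cells, the mature stage therefore made up 60.5% [58.6 to 62.5] in the control library and 54.7% [52.9 to 56.6] in the MCAO library. Erythroid-like cells, the makers of red cells, were 3.97% and 5.91% after red cell lysis. Plasmacytoid-dendritic-like cells, at 2.21% and 2.15%, and T-cell-like cells, at 1.73% and 1.61%, had intervals that overlapped. The smaller classes were macrophage-like cells at 1.65% and 1.15%, basophil-or-mast-like cells at 1.07% and 0.926%, NK-cell-like cells at 0.748% and 0.797%, conventional-dendritic-like cells at 0.576% and 0.926%, and plasma-cell-like cells at 0.192% and 0.111%. The gap in the mature share depended on the cells kept, and was -0.454 percentage points among cells with at least 2000 UMIs and -14.2 points without cluster 9, both chosen after seeing the data.

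**Figure D1:**
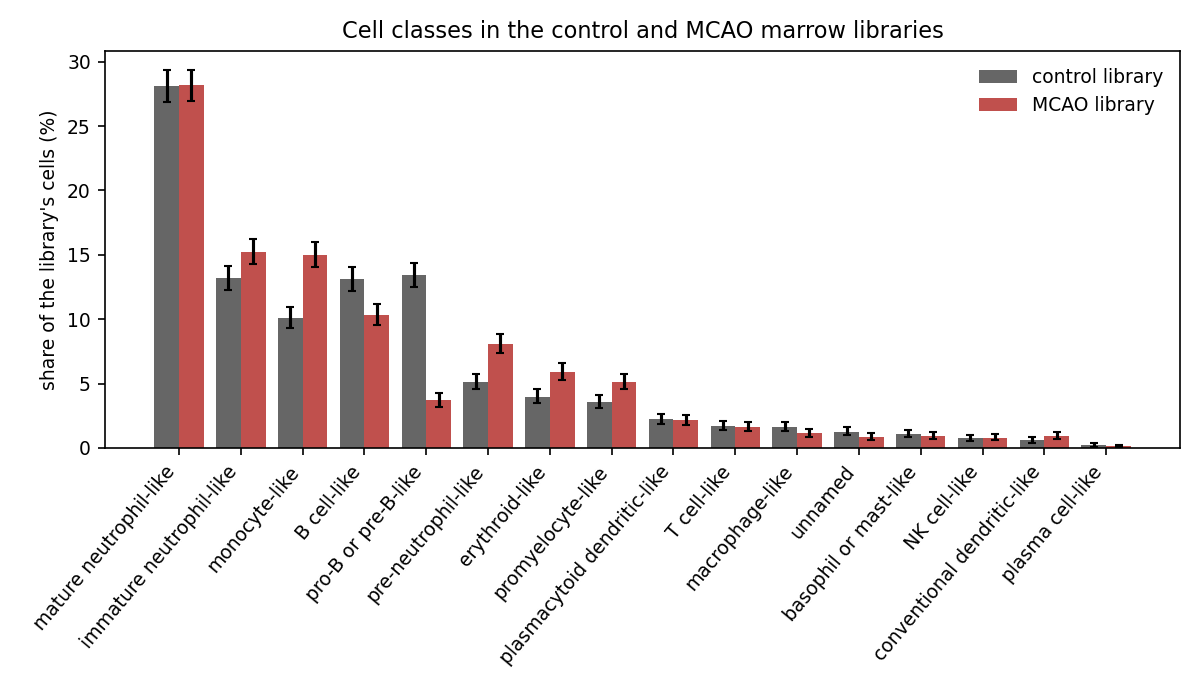
Share of cells (percent, vertical axis) in each rebuilt class in the control and the MCAO library, with exact binomial 95% intervals that cover counting error only. Pro-B-or-pre-B-like cells stand at 13.4% and 3.69%, and monocyte-like cells at 10.1% and 15.0%.

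Cd177, the gene named in the series title, encodes a glycoprotein that sits on the neutrophil surface and in secondary granules. The study title concerns neutrophils that carry it, so its level was followed through the stages. In mature-neutrophil-like cells Cd177 was higher in the MCAO library, at 23.7 [23.3 to 24.1] UMIs per 10000 against 15.9 [15.5 to 16.3], which is 1.49-fold [1.45 to 1.54]. Immature-neutrophil-like cells had the highest level and nearly the same one in both libraries, at 37.2 [36.6 to 37.8] and 38.8 [38.2 to 39.3]. Pre-neutrophil-like cells had 27.8 [27.2 to 28.4] and 29.7 [29.2 to 30.2]. Over all neutrophil-like cells the levels were 26.4 [26.1 to 26.7] and 30.5 [30.2 to 30.8], or 1.15-fold [1.14 to 1.17]. B-cell-like cells, which should lack the gene, carried 2.61 and 3.23, and monocyte-like cells 3.30 and 4.95. Cd177 lies on chromosome 7 from 24743983 to 24760311 on the minus strand of mm10, is annotated as protein coding, and overlaps no other gene. The mature class was held by different clusters in the 2 libraries, namely clusters 2 (74.0%), 3 (24.7%) and 9 (1.23%) in the control library and clusters 3 (44.7%), 9 (29.3%) and 2 (25.99%) in the MCAO library. Within cluster 2 the levels were 8.36 and 10.5 and within cluster 3 they were 28.8 and 33.6, so the log2 ratio of 0.58 over the class was 0.33 and 0.22 within these clusters.

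Cells with at least 1 Cd177 UMI were also more frequent in the MCAO library. In mature-neutrophil-like cells they made up 66.9% [64.5 to 69.3] of control and 83.7% [81.7 to 85.5] of MCAO cells, and in all neutrophil-like cells 79.9% [78.2 to 81.4] and 91.1% [90.0 to 92.1]. Nearly all immature-neutrophil-like cells (99.7% and 100%) and pre-neutrophil-like cells (99.6% and 100%) had the transcript in both libraries. Free RNA put a Cd177 UMI into 32.8% of control and 44.6% of MCAO B-lineage-like cells, whose median depths were 2050.5 and 2198.5 UMIs against 3622.5 and 4693 in neutrophil-like cells. After every cell was thinned to 1000 UMIs the shares were 51.3% [48.7 to 53.9] and 68.5% [66.1 to 70.8] in mature-neutrophil-like cells, with 43 control cells and 0 MCAO cells too shallow to enter. In all neutrophil-like cells the thinned shares were 68.3% and 80.9%, with 51 and 1 cells left out. Thinned B-lineage-like cells stood at 15.7% and 23.7%, with 73 and 6 cells left out. With the 3 stages weighted alike, the difference over all neutrophil-like cells was 5.80 percentage points.

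**Figure D2:**
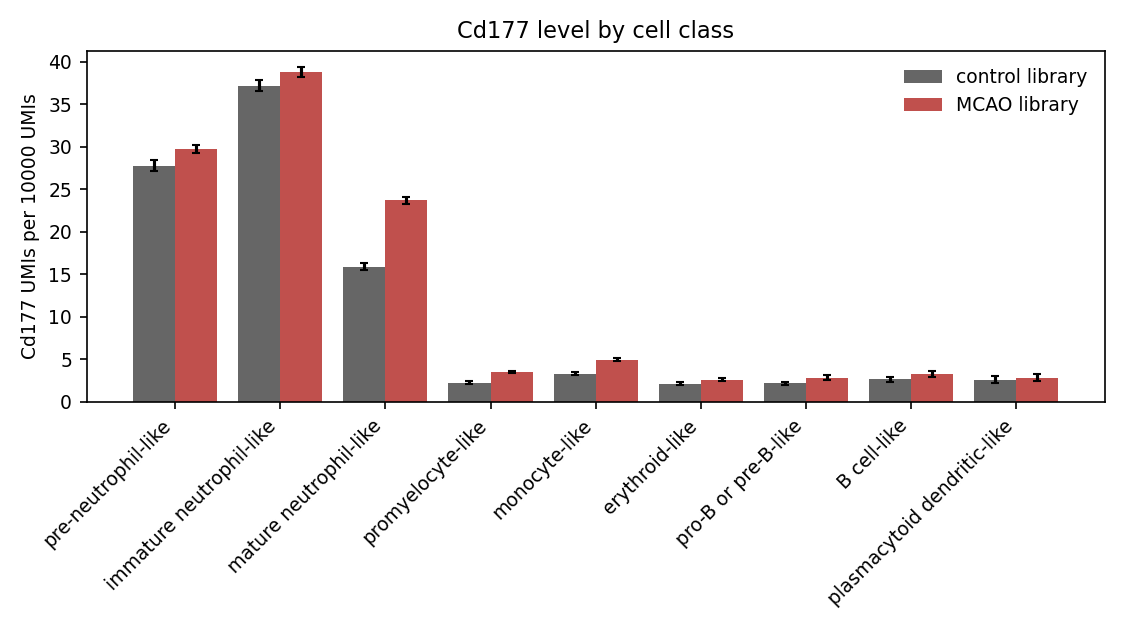
Cd177 level (UMIs per 10000 UMIs of the class) by rebuilt class in the control and the MCAO library, with exact Poisson 95% intervals that cover counting error only. The mature-neutrophil-like class stands at 15.9 and 23.7, and the immature class at 37.2 and 38.8.

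The genes with the highest ratios in mature-neutrophil-like cells were led by stefin A genes, which encode inhibitors of cysteine proteases. Stfa2 had 0.571 [0.5001 to 0.649] UMIs per 10000 in the control library and 7.15 [6.93 to 7.38] in the MCAO library, 12.5-fold [10.98 to 14.3] higher. BC100530, of the same family, was 10.1-fold [8.61 to 11.9] higher (0.405 and 4.08), Stfa1 5.23-fold (0.505 and 2.64) and Stfa3 4.81-fold (0.808 and 3.88). BC117090, a further member, had 3 UMIs against 69, a ratio of 17.3 [5.67 to 85.8]. These 5 genes lie between 36276951 and 36455392 on chromosome 16 as neighbouring copies, so the split of reads between them is uncertain. Wfdc17, which encodes a small secreted protein with a whey acidic protein domain, stood at 2.21 and 5.60 (2.53-fold). Soat2, which esterifies cholesterol, was 3.25-fold higher (0.0586 and 0.190). Prnp, the prion protein gene, was 3.21-fold higher, Med16, a subunit of the Mediator complex, 3.06-fold, and Lrrc75b 3.27-fold. Vcan, which encodes the proteoglycan versican, had 6 and 46 UMIs, or 5.76-fold [2.45 to 16.5], and its levels of 0.0146 and 0.0843 can be free RNA of monocyte-like cells, which had 0.948 and 4.71. Stfa2 and BC100530 were also among the leading genes of cluster 9, in which 96.1% of cells came from the MCAO library and which may be that library rather than a cell type. Within cluster 2 alone the log2 ratio was 1.92 for Stfa2 (3.60 over the class), 1.51 for BC100530 (3.27), 0.84 for Stfa1 (2.34) and 0.50 for Stfa3 (2.24), and without cluster 9 it was 0.12 for Soat2 (1.42) and 0.75 for Wfdc17 (1.33). Vcan and BC100530 overlap genes on the opposite strand, and Prnp overlaps Prn on its own strand, so reads of these pairs cannot be assigned with certainty.

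At the other end stood Thbs1, the gene of thrombospondin 1, an extracellular matrix glycoprotein that binds cells and platelets. Its level in mature-neutrophil-like cells was 4.40 [4.203 to 4.61] in the control library and 0.548 [0.487 to 0.613] in the MCAO library, 8.04-fold lower. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, was 4.72-fold lower (0.952 and 0.202), the stress transcription factor Atf3 5.50-fold (0.544 and 0.0989), and the chemokine gene Ccl3 4.07-fold (0.649 and 0.159). Hcar2, a receptor for hydroxycarboxylic acids, stood at 2.43 and 0.617 (3.93-fold). The nonclassical MHC class I genes H2-Q6 (1.52 and 0.405) and H2-Q7 (1.08 and 0.328) were 3.74-fold and 3.30-fold lower, and the interferon-inducible genes Ifi206 and Pydc3 3.79-fold and 3.18-fold. Acot1, an acyl-CoA thioesterase, was 9.32-fold lower (0.325 and 0.0348), Chac1, which breaks down glutathione, 3.67-fold, and Gla, the lysosomal alpha-galactosidase, 3.43-fold. H2-Q6 (35424850 to 35430055) and H2-Q7 (35439155 to 35443773) are neighbouring copies on chromosome 17 and uncertain as single genes, and Thbs1 (chromosome 2, 118111876 to 118127133, plus strand) and Atf3 overlap genes on the opposite strand. Thbs1 was lower under every setting tried, with log2 ratios from -3.47 to -2.03. In cluster 3 alone the ratio shrank for Atf3 (-2.25 to -0.33), Chac1 (-1.66 to -0.22), Pydc3 (-1.58 to -0.37), Ccl3 (-1.90 to -0.70), Hcar2 (-1.94 to -0.94) and Gla (-1.54 to -0.77), and in cluster 2 alone for Ifi206 (-1.84 to -0.93); Hcar2 is among the leading genes of cluster 2.

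**Figure D3:**
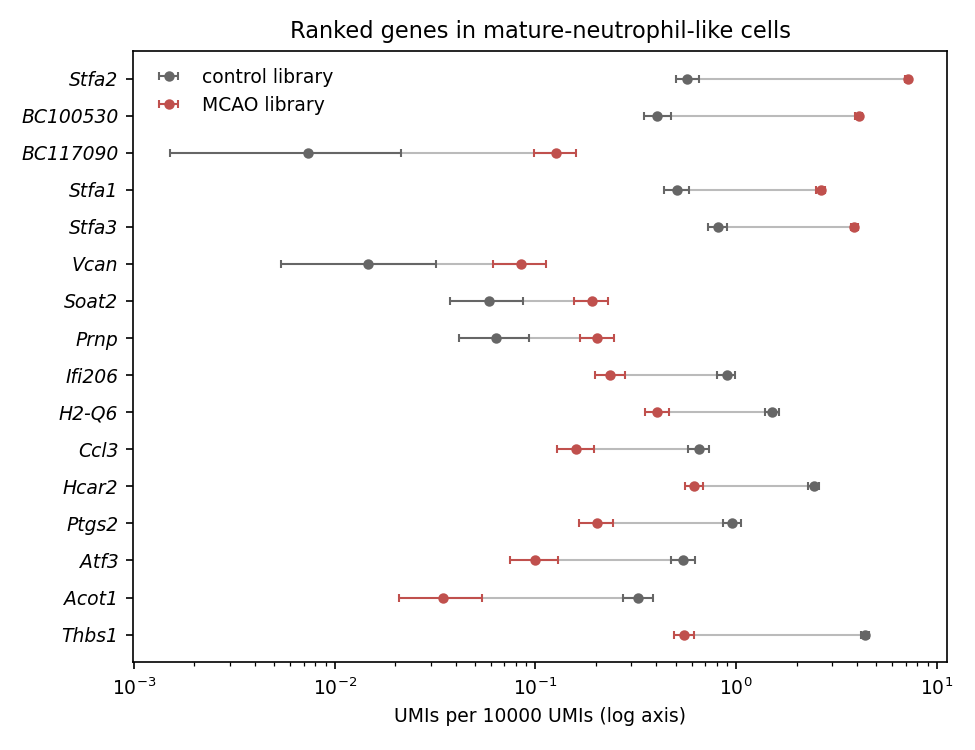
Levels (UMIs per 10000, log axis) of the 8 highest and 8 lowest ranked genes in mature-neutrophil-like cells of the control and the MCAO library, with exact Poisson 95% intervals that cover counting error only. Stfa2 stands at 0.571 and 7.15, and Thbs1 at 4.40 and 0.548.

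Among the fixed lists, interferon response genes, which are induced by type I and type II interferons, were lower in mature-neutrophil-like cells of the MCAO library for 15 of 15 members past the floor, with a median log2 ratio of -0.65. Ifit3 had 10.4 and 4.38 UMIs per 10000, Ifit3b 5.71 and 2.93, Ifit2 1.15 and 0.425, and Ifi47 0.966 and 0.507. MHC class I genes, which present cytosolic peptides, were lower for 9 of 9 members (median -0.50), with H2-K1 at 17.1 and 8.21, B2m at 33.4 and 19.1, Tap1 at 1.40 and 0.958, and Nlrc5 at 0.364 and 0.218. NF-kB inflammatory genes were lower for 9 of 11 (median -0.64), including Ptgs2, Ccl3, Ccl4 (0.398 and 0.145) and Il1rn (5.05 and 2.98), while Tnf and Tnfaip3, named after their values were seen, were higher. Immediate early and heat shock genes, which respond within minutes to stimulation or handling, were lower for 11 of 12 (median -0.47), with Fos at 12.7 and 7.35, Jun at 1.42 and 0.705, and Nr4a1 at 0.351 and 0.207. Each of these 4 medians lay below all 10000 random lists. Glucocorticoid response genes had a median of -0.27 (percentile 0.93), with Per1 at 0.530 and 0.196, Zbtb16 at 0.217 and 0.112, Dusp1 at 14.1 and 9.62, and Tsc22d3 at 2.46 and 1.68. Neutrophil surface receptors had a median of -0.22 (percentile 2.89), with Tlr2 at 1.78 and 1.17, Tlr4 at 0.498 and 0.321, and Csf3r at 12.9 and 10.1, while Ly6g was higher at 9.21 and 11.9. In cluster 2 alone, which is led by Ifit3b, Ifit3 and Ifit1, the interferon median was 0.26 and the MHC class I median 0.03. In cluster 3 alone they were -0.57 and -0.40, and the NF-kB median was -0.03.

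Primary granule genes, which encode the proteases and myeloperoxidase packed at the promyelocyte stage, were higher for 8 of 9 members in the MCAO library, with a median of 0.51 (percentile 100). Ctsc had 0.220 and 0.425 UMIs per 10000, and Prtn3 0.930 and 1.43, the same level as in B-cell-like cells (0.966 and 1.43), which should lack it, so this member lay at the level of free RNA. The list median was 0.44 in erythroid-like, 0.33 in B-cell-like and 0.52 in pro-B-or-pre-B-like cells, so free RNA can give the median in mature-neutrophil-like cells as well. Srgn, the granule proteoglycan and the most abundant member, was lower at 38.6 and 25.7, so the list's summed level was 43.1 and 32.3, opposite in sign to its median. Secondary granule genes had a median of 0.28 (10 of 11 higher, percentile 99.6) and a summed level of 308 and 381, with Olfm4 at 1.13 and 1.80, Ltf at 25.3 and 34.1, Ngp at 95.5 and 121, and Cd177 as given above. This median was -0.23 when the classes came from resolution 2, -0.10 in cluster 3 alone and -0.04 in cells with 2000 to 4000 UMIs. Gelatinase granule genes had a median of 0.13 (percentile 86.6), with Mmp9 at 50.03 and 62.1 and Adam8 at 5.09 and 3.84, and turned below 0 in the same cluster and depth band (-0.17 and -0.07). Cytosolic ribosomal protein genes were higher for 45 of 62 members (median 0.17). Haemoglobin genes, which neutrophils do not make, were higher for 4 of 4 (median 0.88), and B-cell development genes such as Vpreb3 (0.656 and 0.220) were lower for 9 of 9 (median -0.99), as they were in other classes.

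The remaining lists lay within the central 95% of random lists in mature-neutrophil-like cells, with medians from -0.18 to 0.23. NADPH oxidase genes, which encode the enzyme of the oxidative burst, had a median of 0.23 (percentile 95.7), with Ncf4 at 2.20 and 2.82 and Ncf1 at 12.7 and 16.1. Alarmin genes had a median of 0.21 (percentile 91.8), with Anxa1 at 18.98 and 25.8, Lgals3 at 9.81 and 12.9 and S100a6 at 69.4 and 88.0. Glycolysis and hypoxia genes had a median of 0.08 (percentile 90.8) and cell cycle genes 0.06 (percentile 73.1). The G-CSF and STAT3 response list stood at -0.01 (percentile 56.9), with Pim1 at 5.84 and 7.98, and the marrow retention and egress list at -0.02 (percentile 48.8), with Cxcr4, the receptor that holds neutrophils in marrow, at 6.41 and 4.86 and S1pr4 at 1.29 and 1.81. Apoptosis genes had a median of -0.06 (percentile 24.6), with Pmaip1 at 0.393 and 0.180, and MHC class II genes -0.18 (percentile 14.7), with Cd74 at 1.55 and 1.05. Of the 20 lists with a value, 10 lay outside the central 95% of random lists, among them the haemoglobin and B-cell development lists. In simulated data 8.50% of unchanged lists did so. The simulated cells shared 1 mean profile, and their lists were random genes. That simulation held no genes that vary together, no cluster mix and no free RNA, so it gives no rate for the fixed lists here.

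**Figure D4:**
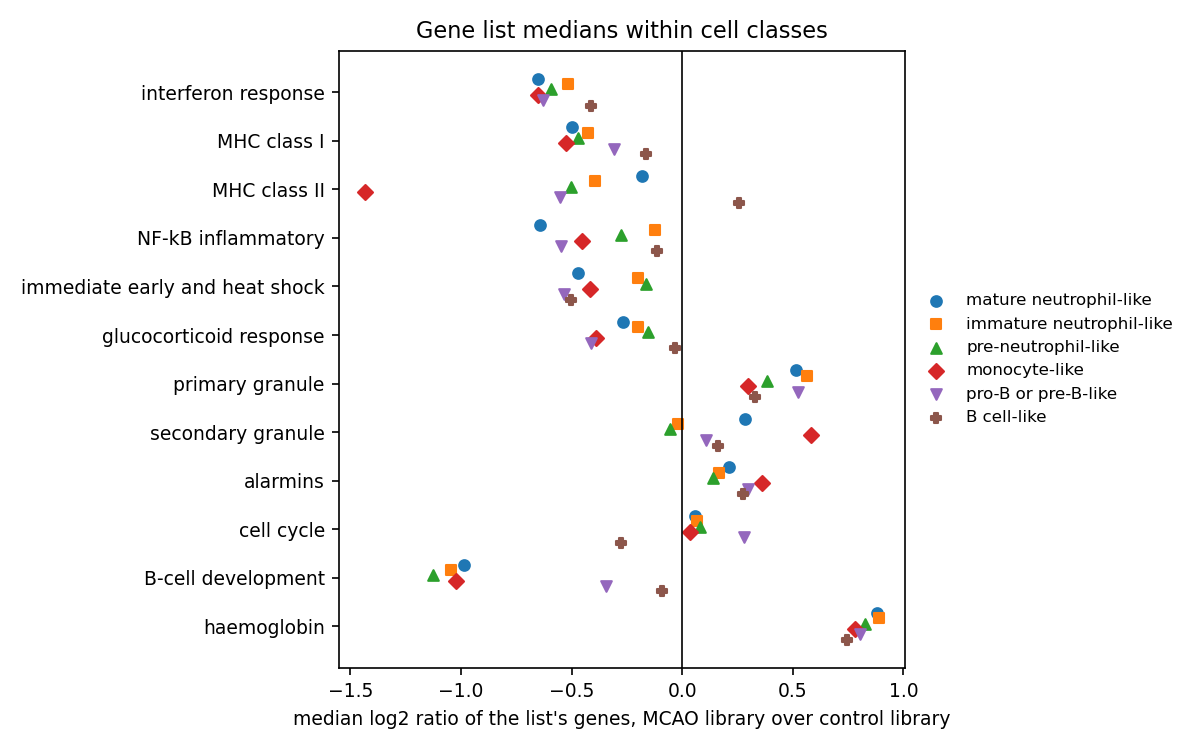
Median log2 ratio (MCAO over control, horizontal axis) of 12 fixed gene lists in 6 rebuilt classes; a value above 0 is a higher level in the MCAO library. The interferon response points lie below 0 in each class, and the MHC class II point of monocyte-like cells is the lowest, at -1.43.

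In immature-neutrophil-like cells Stfa2 had 14 UMIs in the control and 273 in the MCAO library, 14.6-fold [8.55 to 27.1] higher, but its MCAO level of 0.559 per 10000 was that of B-cell-like cells (0.542), so free RNA alone can give this ratio. BC100530 was 16.9-fold [8.72 to 37.5] higher, Stfa1 3.37-fold, and Rbks, a ribokinase gene, 4.19-fold. Thbs1 was 5.69-fold lower (3.21 and 0.565), Hcar2 4.67-fold, H2-Q6 3.43-fold and the kinase anchor gene Akap12 3.89-fold. The levels of Akap12 (0.175 and 0.0450), a leading gene of the pro-B-or-pre-B-like cluster 7, and of H2-Q6 (0.421 and 0.123) were near or below those of erythroid-like cells (0.160 and 0.0592, and 0.700 and 0.255), so these ratios can come from free RNA. Interferon response genes were lower for 14 of 15 members (median -0.52), with Oasl2 at 4.26 and 2.45 and Ifit1 at 1.67 and 0.935, and MHC class I genes for 7 of 9 (median -0.43), with H2-K1 at 9.05 and 4.75 and B2m at 25.9 and 17.5. Primary granule genes had a median of 0.57, with Elane, the neutrophil elastase gene, at 1.37 and 2.05 and Prtn3 at 0.735 and 1.23, below the 1.84 and 2.34 and the 0.966 and 1.43 of B-cell-like cells, so neither stood above free RNA. Ribosomal protein genes had 0.33 (55 of 65 higher), and alarmins 0.16 (percentile 98.8). Secondary granule genes, which define this stage, stood at -0.02 (5 of 11 higher, percentile 16.1). Glucocorticoid response genes had a median of -0.20 and a summed level of 64.6 and 69.2, which differ in sign. MHC class II genes had -0.39 (percentile 0.505) and immediate early and heat shock genes -0.20 (percentile 0.47). In pre-neutrophil-like cells Stfa2 had 1 and 149 UMIs, a ratio of 86.4 [15.3 to 3433] at an MCAO level of 0.323, below that of B-cell-like cells and near the 0.365 of erythroid-like cells, so it too can come from free RNA. BC100530 was 11.3-fold higher there, Asprv1, a retroviral-like aspartic protease gene, 3.02-fold, and the desaturase gene Scd2 2.93-fold. Dusp5, a phosphatase of ERK kinases, was 4.96-fold lower there, Akap12 4.54-fold, Thbs1 4.52-fold and H2-Q6 3.48-fold. Of these, Asprv1 (0.142 and 0.429), Akap12 (0.187 and 0.0412), Thbs1 (0.284 and 0.0629) and H2-Q6 (0.550 and 0.158) also had MCAO levels near or below those of erythroid-like cells (0.478, 0.0592, 0.0540 and 0.255), and Dusp5 (0.172 and 0.0347) was far below its level in B-lineage-like cells (2.53 and 0.982), so free RNA can give these ratios as well. The interferon median in this stage was -0.59 and the primary granule median 0.38. At resolution 2 the immature medians turned from -0.07 to 0.15 for gelatinase granule genes, from -0.06 to 0.08 for surface receptors and from -0.05 to 0.03 for retention and egress.

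In B-lineage-like cells MHC class II genes, which present peptides to T cells, were higher in the MCAO library for 7 of 7 members, with a median of 0.67 and a summed level of 68.6 and 105. This value joined classes that went apart. In B-cell-like cells the median was 0.26 (7 of 7 higher, percentile 99.8), with Ciita, the transactivator of these genes, at 2.62 and 3.71 and H2-Aa at 32.7 and 40.5. In pro-B-or-pre-B-like cells it was -0.55 (0 of 6 higher), with Cd74 at 3.60 and 1.52. Cell cycle genes also went apart, with a median of 0.28 and 17 of 17 higher in pro-B-or-pre-B-like cells, such as Mcm5 at 2.53 and 3.70, and -0.27 with 2 of 16 higher in B-cell-like cells. B-cell development genes had a median of -0.35 in pro-B-or-pre-B-like cells. Rag1, which cuts antigen receptor genes, was lower at 6.16 and 3.63, while the early genes Vpreb1 (3.50 and 6.28) and Igll1 (3.55 and 4.76, named after its value was seen), which form the surrogate light chain, and Dntt (2.26 and 3.57) were higher. The clusters within both classes differed in share, so these values can reflect the mix. Clusters 7, 14 and 21 held 68.7%, 23.1% and 8.14% of control and 54.8%, 31.2% and 14.1% of MCAO pro-B-or-pre-B-like cells, where cluster 7 is led by Rag1 and cluster 21 by Vpreb1, Dntt and Igll1. Cluster 6, whose leading genes include Ciita, held 49.9% of control and 64.1% of MCAO B-cell-like cells, and cluster 8 held 48.1% and 33.6%. Interferon response genes were lower in all B-lineage-like cells (median -0.36), in B-cell-like cells (-0.41) and in pro-B-or-pre-B-like cells (-0.63). Immediate early and heat shock genes had a median of -0.50 in B-cell-like cells, with Nr4a1, induced by antigen receptor signals, at 2.14 and 0.754 and Fos at 1.39 and 0.776.

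The ranked ends of the B-lineage classes were filled by genes of few UMIs. Over B-lineage-like cells the highest were Stfa2 (9.35-fold), Stfa3 (7.17-fold), BC100530 (6.97-fold) and Vpreb2, a surrogate light chain gene (3.97-fold). The first 3 are neutrophil transcripts, which were also the highest genes of erythroid-like cells. Stfa2 had 0 and 9 UMIs in T-cell-like cells as well. The lowest were Prm1 (6.28-fold lower), Fam72a (5.64-fold), Neto2 (5.26-fold) and Rbm24 (3.69-fold). In pro-B-or-pre-B-like cells Vpreb2 was 5.62-fold higher (15 and 36 UMIs), Tbl2 and Zfp428 3.51-fold and Gcsh 3.29-fold. H2-Q5 had 56 and 1 UMIs there, a ratio of 0.0418 [0.00104 to 0.243], and Gem 55 and 3, a ratio of 0.128 [0.0256 to 0.394]. Susd3 was 5.66-fold lower, and Ms4a1, which encodes the B-cell antigen CD20, 4.29-fold. In B-cell-like cells Stfa2 had 2 and 74 UMIs (42.4 [11.3 to 356]), Stfa2l1 was 3.24-fold higher, Mocs3 2.71-fold and Gatm 2.67-fold. Rapgefl1 was 4.31-fold lower, Coq7 3.45-fold, the interleukin 2 receptor gene Il2ra 3.33-fold and Eaf2 3.25-fold. Stfa2l1 (0.333 and 1.08) is a marker of the mature neutrophil class and a leading gene of cluster 9. Il2ra (0.269 and 0.0806) is a leading gene of the pro-B-or-pre-B-like cluster 7. Free RNA can therefore give part of both ratios.

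Monocyte-like cells had the lowest list median of any class, for MHC class II genes. The median was -1.43 with 6 of 7 members lower and below all 10000 random lists, as H2-Eb1 had 1.36 and 0.373 UMIs per 10000, H2-Aa 2.74 and 0.879, H2-Ab1 2.60 and 0.932, and Cd74 5.39 and 1.98. Clusters 4, 11 and 20 held 57.6%, 31.2% and 11.2% of control and 61.8%, 32.9% and 5.32% of MCAO monocyte-like cells, and the part of this mix in the median was not tested. Saa3, an acute-phase serum amyloid gene, had 0 UMIs in the control library and 170 in the MCAO library. It was above 0 in 5.07% of the MCAO monocyte-like cells. Its fold against the floor of 3 UMIs was 30.6, and its lower counting limit was 24.6. Vcan was 4.97-fold higher (0.948 and 4.71), F11r, a junctional adhesion molecule gene, 8.82-fold (9 and 147 UMIs), and BC100530 had 3 and 173 UMIs, a ratio of 31.2 [10.5 to 153]. The MCAO level of BC100530, 0.242, was that of free RNA, with 0.235 in B-lineage-like and 0.208 in erythroid-like cells. Among the lowest, the interferon-induced genes Ifi44 and Iigp1 were 4.40-fold and 7.26-fold lower, and H2-Q6 and H2-Q7 4.39-fold and 3.89-fold, with MCAO levels of 0.242 and 0.274, below the 0.255 and 0.419 of erythroid-like cells. Interferon response genes were lower for 16 of 16 (median -0.65), with Usp18 at 1.15 and 0.548, MHC class I genes for 9 of 9 (median -0.52) and NF-kB inflammatory genes for 12 of 13 (median -0.45). Glucocorticoid response genes had a median of -0.39. Alarmin genes were higher (median 0.36, summed level 160 and 217), of which free RNA can be a large part, as B-cell-like cells had 164 and 189 and erythroid-like cells 130 and 151. Also higher were secondary granule genes (median 0.58, summed level 108 and 163). Secondary granule genes were also higher in B-lineage-like cells (median 0.25), so free RNA can be part of this rise. The list's summed level was 85.0 and 94.9 in B-cell-like and 58.25 and 63.24 in erythroid-like cells. Both gaps are smaller than that in monocyte-like cells, whose source was not tested. Vcan is also among the genes that set cluster 4 apart within this class.

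Promyelocyte-like, erythroid-like and plasmacytoid-dendritic-like cells completed the compared classes. In promyelocyte-like cells the platelet genes Pf4 (11 and 206 UMIs, 10.8-fold) and Ppbp (1 and 69 UMIs, 39.8 [6.90 to 1593]) were the highest, with BC100530 (2 and 70 UMIs, 20.2 [5.38 to 170]) and the growth factor gene Clec11a (4 and 87 UMIs, 12.5-fold). The MCAO level of BC100530, 0.149, was below that of B-lineage-like and erythroid-like cells, so its ratio can come from free RNA. Akap12 was 5.54-fold lower, Rps2-ps10 5.21-fold, the interleukin 7 receptor gene Il7r 4.34-fold and Cox6a2 3.72-fold. Akap12 (0.248 and 0.0448) and Il7r (0.315 and 0.0726) are transcripts of pro-B-or-pre-B-like cells, where they had 10.7 and 8.25, and 10.5 and 8.60, so their ratios here can come from free RNA too. Their interferon median was -0.74 (0 of 15 higher) and their primary granule median 0.23, with a summed level of 262 and 292. Their glucocorticoid median of -0.34 was opposite in sign to the summed level of 10.2 and 12.8. Erythroid-like cells had higher haemoglobin genes (summed level 389 and 581), with a median of 0.58 that was the lowest of the 9 classes. Cluster 24, whose leading genes include Hba-a1, held 20 of 207 control and 51 of 319 MCAO erythroid-like cells, so the mix can be part of this. Interferon genes were lower in erythroid-like cells (median -0.65). Stfa2 (4 and 142 UMIs, 22.8-fold), BC100530 (13.02-fold), Stfa3 (3.86-fold) and Wfdc17 (3.10-fold) were highest there, and the histone gene Hist1h2ae (6.90-fold), Rps2-ps10 (4.67-fold) and the interferon-induced genes Ifi44 and Tgtp2 (each 4.41-fold) were lowest. In plasmacytoid-dendritic-like cells, the main makers of type I interferon, MHC class II genes were lower for 6 of 6 (median -0.43, summed level 73.2 and 53.8) and cell cycle genes higher for 13 of 15 (median 0.32), while the interferon median was -0.17 (percentile 9.14). Thap11 (4.199-fold), Asprv1 (3.44-fold), Ncapg2 (3.25-fold) and Hmmr (2.97-fold) were highest and Vpreb3 (11.4-fold), the chemokine gene Ccl4 (6.62-fold), Inpp5k (4.67-fold) and Tfeb (3.50-fold) lowest. Free RNA can give part of the ratios of Asprv1, a leading gene of cluster 9 (0.234 and 0.805, against 0.212 and 0.478 in erythroid-like cells), and of Vpreb3, a B-lineage transcript (0.974 and 0.0856, against 0.684 and 0.262). Over the 9 compared classes, interferon medians ran from -0.74 to -0.17 and MHC class I medians from -0.57 to -0.16, all below 0. The summed interferon levels of B-cell-like (23.2 and 18.1), pro-B-or-pre-B-like (17.3 and 12.8), promyelocyte-like (21.8 and 14.1) and pre-neutrophil-like cells (25.9 and 17.2) lay below those of erythroid-like cells (28.4 and 20.2), so free RNA can give part of the shared direction. Primary granule, alarmin and NADPH oxidase medians were all above 0, a direction that free RNA shares, as erythroid-like cells had Elane at 1.71 and 2.34, Mpo at 1.34 and 1.85 and S100a8 at 54.9 and 68.2. The T-cell-like class, with 90 and 87 cells, was not compared.

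The series title sets apart neutrophils that carry Cd177, so cells with and without a Cd177 UMI were compared within each library at matched depth. Only mature-neutrophil-like cells had enough cells without it, 695 with and 477 without in 4 depth bins of the control library and 380 and 228 in 2 bins of the MCAO library. Cells with Cd177 had more secondary granule transcripts, with medians of 0.60 in the control and 0.31 in the MCAO library (9 and 6 of 10 members higher, Cd177 left out). The 8 markers of the immature stage were all higher in both (medians 0.66 and 0.60), while the markers of the mature stage stood at -0.10 and -0.10. Gelatinase granule genes (0.30 and 0.33) and alarmins (0.30 and 0.38) were higher in these cells. Interferon response genes (-0.23 and -0.35), MHC class I genes (-0.20 and -0.21) and immediate early and heat shock genes (-0.30 and -0.38) were lower. Glucocorticoid response genes stood at -0.42 and -0.13 and NF-kB inflammatory genes at -0.03 and -0.60, and of these the MCAO glucocorticoid value and the control NF-kB value had counting intervals that included 0. The lists of secondary granules and of interferon response depended on the clusters, as their medians within cluster and depth bins, chosen after seeing the data, were 0.25 and 0.03 for the former and -0.11 and 0.09 for the latter.

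Single genes had little in common between the libraries in this contrast. Of 5629 genes, 56.0% had the same sign in both, and the correlation across genes, which are not independent replicates, was 0.11. The genes highest in cells with Cd177 had few UMIs. They were Acvrl1, a receptor kinase of the TGF-beta family (log2 ratios 2.77 and 1.45, with 111 and 5 UMIs in control cells with and without Cd177), Gfpt1, the entry enzyme of hexosamine synthesis (1.53 and 1.95), the secreted chemoattractant gene Prok2 (47 and 3 UMIs in the control and 18 and 0 in the MCAO library), Dcun1d3 (1.91 and 1.96), Pax5 (1.86 and 1.95), Fbxl18 (1.78 and 1.86), Xab2 (1.57 and 2.12) and Kif11 (1.55 and 1.67). The lowest were Atf3 (-1.90 and -2.60, with 63 and 148 UMIs in control cells), the pro-apoptotic gene Pmaip1 (-1.49 and -1.35), Slc12a9 (-1.41 and -1.45), Arhgap5 (-1.38 and -1.87), Ino80b (-1.34 and -1.43), Mtch2 (-1.35 and -1.33), Zfp729b (-1.76 and -1.32) and Col11a2 (-1.31 and -2.05). These log2 ratios are averages over depth bins and can differ from the ratio of the levels in either direction. In MCAO cells with and without Cd177, Gfpt1 had levels of 0.362 and 0.227, a smaller gap than 1.95. Pax5 had 0.120 and 0.0189 there, a wider gap than 1.95. In the control and MCAO libraries Pax5 had 10.1 and 10.9 in B-cell-like cells, and 0.164 and 0.0823 in erythroid-like cells. Free RNA can therefore give its UMIs in mature-neutrophil-like cells. A cell without a Cd177 UMI may still carry the transcript at this depth.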

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

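The tests within clusters, maturity bins and the depth band and with at least 2000 UMIs were chosen after the data were seen, the maturity bins only when the test within clusters had left its question undecided, and the tests of Cd177 and of B-lineage dilution were chosen after their own results were seen.

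3 gene lists pointed in opposite directions in different classes, each by a median of at least 0.2 on the log2 scale and beyond the 1st or 99th percentile of random lists, and these differences between classes were not tested. MHC class II genes had medians of 0.26 in B-cell-like, -1.43 in monocyte-like, -0.55 in pro-B-or-pre-B-like, -0.50 in pre-neutrophil-like, -0.43 in plasmacytoid-dendritic-like, -0.39 in immature-neutrophil-like and -0.29 in promyelocyte-like cells. The summed levels in pre-neutrophil-like (3.57 and 2.37), immature-neutrophil-like (2.92 and 2.25) and promyelocyte-like cells (4.03 and 2.95) were near those of erythroid-like cells (3.70 and 2.95), so these 3 values cannot be told apart from free RNA. Cell cycle genes had medians of 0.32 in plasmacytoid-dendritic-like, 0.28 in pro-B-or-pre-B-like and -0.27 in B-cell-like cells. Marrow retention and egress genes had medians of 0.22 in B-cell-like and -0.21 in monocyte-like cells. The former is the value of Cxcr2 (1.22 and 1.43), a neutrophil transcript, while Cxcr4 was lower in B-cell-like cells (7.76 and 4.48), so this median cannot be told apart from free RNA.

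Interferon response genes were lower in mature-neutrophil-like cells of the MCAO library, with a wider gap in summed level than in the other classes. The relative gap was not the widest there. Over the 9 compared classes the list median ran from -0.74 (promyelocyte-like) to -0.17 (plasmacytoid-dendritic-like), and it was -0.65 in mature-neutrophil-like cells. B-cell-like, pro-B-or-pre-B-like, promyelocyte-like and pre-neutrophil-like cells had summed levels below those of erythroid-like cells (28.4 and 20.2), so free RNA can give part of their gap. Free RNA that differs between the libraries would lower every class by a like amount, but the summed level differed by 34.7 UMIs per 10000 in mature-neutrophil-like and by 5.10 in B-cell-like cells, a ratio of 6.80. Deeper MCAO cells and a less mature mix of cells were also argued against, since the median was -0.66 in cells with 2000 to 4000 UMIs and -0.55 as the mean over 5 bins of immature marker share, from -0.68 to -0.40. Different mature clusters in the 2 libraries cannot be told apart from a lower response, because the median was 0.26 in cluster 2 and -0.57 in cluster 3 and cluster 2 was itself sorted by interferon genes. A lower interferon tone in marrow after stroke may account for the pattern, as may a difference between the 2 libraries, their animals or their handling, none of which 1 library per group can separate.

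Pro-B-or-pre-B-like cells were 13.4% of the control and 3.69% of the MCAO library. Dilution by more myeloid cells would leave their number per B-cell-like cell unchanged, but it was 1.02 in the control and 0.357 in the MCAO library, a ratio of 0.349. Shallow cells kept more often in the control library were argued against by cells with at least 2000 UMIs, where the shares were 10.0% and 2.77%, a ratio of 0.277. A loss of B-cell precursors after stroke may account for the pattern, and a difference between the libraries or animals stays open as well.

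The higher Cd177 level of mature-neutrophil-like cells was not the work of free RNA alone, since Cd177 differed by 7.81 UMIs per 10000 there and by 0.621 in B-cell-like cells, a ratio of 12.6. A different mix of mature clusters was argued against as the whole cause, since the log2 ratio was 0.33 within cluster 2 and 0.22 within cluster 3, with counting intervals above the bound set for it. That bound was rewritten after the values were seen. The mix may account for part of the class ratio of 0.58, because both values within clusters are smaller. More Cd177 per mature neutrophil after stroke and a difference between the libraries both stay open.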

How the results depend on the processing

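Settings that name single clusters, cluster 9, depth bands or minimums of 2000 UMIs, other denominators, maturity bins or B-lineage classes apart were chosen after seeing the data. Values were held to their counting interval. Counts of lists, and of named genes in mature-neutrophil-like cells, have no such interval and were held to a fixed factor of the main value instead. Counts of named genes in the other classes were held to no bound. No pseudocount, no floor, unmatched random lists, 1000 variable genes and thinning moved no result beyond its bound, out of 191, 21, 1, 6 and 3 results tried. Over all settings, the results that answer a comparison stayed within that bound 135 times, moved beyond it 40 times and changed sign 4 times, and the other results 1193, 314 and 13 times. Depth limits the low genes, as most genes at the ranked ends rest on few UMIs in 1 of the libraries.

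The difference in the neutrophil-like share was 0.865 points without cluster 9. For B-lineage-like cells it was -8.98 points with at least 2000 UMIs and -20.8 among cells that are not neutrophil-like, and for monocyte-like cells 3.47 and 12.04. The mature share differed by -12.8 points at resolution 2, -0.454 with at least 2000 UMIs and -14.2 without cluster 9. The Cd177 log2 ratio in neutrophil-like cells was 0.35 from mean linear values, 0.18 centred on the median gene and 0.29 without cluster 9. The share with Cd177 differed by 14.6 points at 2 or more UMIs, 5.80 with stages weighted alike and 14.6 without cluster 9.

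In mature-neutrophil-like cells the medians at resolution 2 were -0.23 for secondary granule, -0.49 for interferon and -0.38 for NF-kB genes. Without cluster 9 the interferon median was -0.46 and the NF-kB median -0.80. In cluster 2 alone gelatinase granule stood at -0.0082, interferon at 0.26, NF-kB at -0.37 and MHC class I at 0.031. In cluster 3 alone secondary granule stood at -0.10, gelatinase granule at -0.17, interferon at -0.57, NF-kB at -0.029, MHC class I at -0.40 and apoptosis at 0.0017. Cells with 2000 to 4000 UMIs gave -0.0365 for secondary granule, -0.067 for gelatinase granule, -0.26 for NF-kB and -0.31 for MHC class I. Maturity bins gave -0.55 for interferon, -0.47 for NF-kB and -0.36 for MHC class I. Of the 24 genes that the naming rule takes, 9 were also taken from cluster 2 alone, 10 from cluster 3 alone and 15 from cells with 2000 to 4000 UMIs, where fewer cells were used. Of 8 genes each in the other classes, the naming rule took again 4 in monocyte-like cells with no pseudocount, 1 in promyelocyte-like cells at resolution 2 and 3 with a pseudocount of 0.1, 3 in erythroid-like cells from mean linear values, and 2 in plasmacytoid-dendritic-like cells at resolution 0.5. Immature-neutrophil-like medians at resolution 2 were 0.15 for gelatinase granule, 0.083 for surface receptors and 0.028 for retention and egress.

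In B-lineage-like cells MHC class II stood at 0.73 from mean linear values, 0.26 in B-cell-like and -0.55 in pro-B-or-pre-B-like cells only, and the latter gave -0.63 for interferon and 0.28 for cell cycle. For cells with against without Cd177, leaving out depth bins gave 1.68 (control) and 1.72 (MCAO) for secondary granule and -0.71 and -1.05 for interferon, and bins within clusters gave 0.25 and 0.028, and -0.11 and 0.092. In the MCAO library haemoglobin stood at 0.0402 with 2 or more UMIs, and retention and egress at 0.017 in bins within clusters. Beyond the settings whose own construction keeps fewer cells or classes, the cause was not tested.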

Other observations

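The choice of the clock genes and of the macrophage-like genes below followed from values already seen, and the requirement of at least 3 genes per arm in the clock test was set after its result was seen.

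Macrophage-like cells of the marrow, which engulf ageing neutrophils as part of their normal work, carried high levels of neutrophil transcripts in the MCAO library. Over 86 control and 62 MCAO cells, S100a8 had 272 and 418 UMIs per 10000, Ngp 161 and 279, Ltf 48.2 and 95.5, Camp 35.5 and 80.1, and Cd177 11.5 [10.5 to 12.6] and 21.4 [19.9 to 23.0]. Stfa2 had 0 UMIs there in the control library and 97 in the MCAO library. B-cell-like cells had 28.7 and 29.5 for Ngp, 7.86 and 8.53 for Ltf, and 8.72 and 9.84 for Camp. T-cell-like cells had 15.8 and 22.5 for Ngp, 3.86 and 7.83 for Ltf, 5.60 and 6.94 for Camp, 1.32 and 2.95 for Cd177, and 46.2 and 74.1 for S100a8. Levels in macrophage-like cells were above those of both classes, but the ratios of the libraries for Ltf, Cd177 and S100a8 were like those of T-cell-like cells. The haemoglobin gene Hba-a1 went the other way in macrophage-like cells, at 10.4 and 8.27, against 4.13 and 7.34 in B-cell-like cells. The median depth of macrophage-like cells was 3194.5 and 5958.5 UMIs.

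Division genes stood higher over the neutrophil-like cells as a whole. All 17 cell cycle genes were higher in the MCAO library over the 3 stages together, with a median of 0.28, while the medians within stages were 0.08 in pre-neutrophil-like, 0.07 in immature and 0.06 in mature cells. Pre-neutrophil-like cells, which hold most of these transcripts, were 11.04% of neutrophil-like cells in the control and 15.7% in the MCAO library. The platelet genes Pf4 and Ppbp in promyelocyte-like cells came from few cells, as 2.16% of control and 6.16% of MCAO cells of that class had a Pf4 UMI.

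Per1, a gene of both the circadian clock and the glucocorticoid response, was lower in the MCAO library in 8 of 8 classes in which it passed the floor, with log2 ratios from -1.35 to -0.69. Erythroid-like cells had Per1 at 0.480 and 0.242. It lay below that in immature-neutrophil-like (0.194 and 0.113), pre-neutrophil-like (0.157 and 0.0607), promyelocyte-like (0.352 and 0.162) and pro-B-or-pre-B-like cells (0.2715 and 0.0964). Free RNA can therefore give part of the shared direction. Marrow taken at different times of day may account for the lower Per1, and would also lower other clock output genes against the activator genes. The arm set as activator genes also held Nfil3, which encodes a repressor. It was Nfil3 alone in immature-neutrophil-like, pre-neutrophil-like and erythroid-like cells, so the differences there did not compare output genes with activators. The median difference between these arms was -0.079 over 7 classes, with a range from -1.12 to 1.37 and 4 of the 7 below 0. This lay within the bound of 0.2 written beforehand as evidence against the idea, but not beyond its spread, and the only 1 of 9 classes with 3 genes in each arm, promyelocyte-like cells, had a difference of 0.41, which goes against the idea in that class. The time of day therefore cannot be told apart from a lower glucocorticoid or stress signal with these genes.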
